A study of Absidia caerulea with 2 samples.

How the data were processed

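The series holds 2 RNA-seq libraries made from mycelia of wild-type Absidia caerulea, a filamentous fungus of the Mucorales, strain AS3.65. The series' own text also calls the organism A. orchidis and A. coerulea, and the names were taken as the labels give them. Young mycelia grown in potato dextrose broth were moved to 30 ml of potassium phosphate buffer and kept there for 2 h, either with N,N-dimethylformamide alone (mock, 1 library) or with 170 mg/L of RSA, 11-deoxycortisol 21-acetate, dissolved in that solvent (RSA, 1 library). Per the labels' protocols, total RNA was extracted with Trizol and phenol-chloroform, treated with DNase I on a column, and made into Illumina libraries. Whether strand was kept is not given in the sources used here.

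The deposited tables are gene-level outputs of RSEM, a program that divides reads that align to several transcripts among them. Per the submitters' processing notes, RSEM 1.2.0, Bowtie2 and Trimmomatic were used. Their parameters, and which reads were assembled, are not given in the sources used here. Each row is a component of a transcriptome assembly whose identifiers begin with TRINITY, here called a feature. Per the file headers, the authors deposited for each feature an expected count (an estimated number of reads or fragments that need not be whole), a TPM value (abundance divided by effective length and scaled to the same sum in each library) and an FPKM value (scaled by effective length and library size). FPKM as deposited is TPM times 1 constant per library and was not analysed further. The tables also give a length, averaged over a feature's transcripts by their abundance, and an effective length, both in nucleotides. The files pair no feature with a gene name, description or sequence, and no genome or annotation was used here. The 25 gene lists fixed before the data were examined, cytochrome P450 enzymes and their redox partners among them, were defined by description, so none of them was analysed here. Genome coordinates are not given for the same reason.

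Both tables list 45338 features in the same order. The expected counts sum to 8904820 in mock and 8923379 with RSA, and 81.8% and 82.8% of the values are exactly whole. They were rounded to whole numbers for all count-based steps. Features with at least 20 rounded counts over both libraries were compared. The libraries were scaled with TMM (edgeR 4.0.16, R 4.3.3), which sets the effective size of the RSA library to 0.939 of that of the mock library.

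With 1 library per group there is no estimate of the spread between cultures, no test between conditions was made and no p-value is given. A feature was called higher or lower by a fixed rule of size: the scaled ratio of RSA over mock was at least 2-fold and its exact 95% conditional binomial (Clopper-Pearson) interval excluded equality. These intervals cover counting error only, not the division of shared reads by RSEM, not amplification and not the difference between cultures. The difference between the libraries has no replicate check. A count of 0 was set to a floor of 3 counts per library (0.337 CPM in mock and 0.336 CPM with RSA). A fold against it is a bound set by that floor and is given as "at least". The limit of the 95% counting interval is less extreme than this bound. The rule for named features, fixed before the data were examined, took the 2 features with the highest lower interval bound and the 2 with the lowest upper bound among those with at least 50 counts over both libraries. Other features and clusters are given without identifiers.

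The shared stem of an identifier marks features that the assembler built from 1 connected group of sequences, here called a cluster. The 45338 features fall into 34166 clusters, of which 27401 hold 1 feature, and the rest hold up to 126. Because reads of near-identical features can be divided between them in different ways, the comparison was repeated on counts summed over each cluster. This step was chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

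The procedure was tested on simulated data, with Poisson counts at the real means and library sizes for all 45338 features and 200 features changed by known folds. It called 33 of 65 features changed 2-fold, 65 of 66 changed 4-fold and 63 of 63 changed 8-fold in the true direction, and none in the wrong direction. Of 14835 unchanged features, 33 were called higher and 62 lower. This simulation holds counting error only. Alternatives were other scalings (library totals, DESeq2 1.42.0 size factors, upper quartile, TMM without the 20 most abundant features), count minimums of 1, 10 and 100, a 4-fold rule, an interval wholly beyond 2-fold, and TPM plus 1 in place of counts. The correlation between libraries was computed on log2(CPM + 1) and repeated with other settings.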

Results

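Transcript abundance in Absidia mycelium exposed to a steroid substrate was compared with that in mycelium exposed to its solvent. RSA is the 21-acetate of 11-deoxycortisol, the compound that an 11β-hydroxylase converts to hydrocortisone. The series title names the identification of this fungus' 11β-hydroxylation system, and the comparison asks which transcripts were more abundant 2 h after the substrate was added. Each group had 1 library, so no value below carries a replicate error. The mock library held 8904802 rounded counts and the RSA library 8923366. A count was present for 35535 of 45338 features in mock and for 29223 with RSA. The 100 most abundant features took 27.1% of the mock counts and 27.9% of the RSA counts. Feature length had a median of 431 nucleotides (nt) and reached from 201 to 16092 nt in the mock table, and 40761 features had 1 transcript.

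The libraries were similar for most features. Among the 14962 features with at least 20 counts over both libraries, log2(CPM + 1) gave Pearson's r = 0.959 and Spearman's rho = 0.955. These values are across features, which are not independent replicates. The scaled ratio of RSA over mock lay within 1.5-fold for 78.9% of the compared features. This share was 56.2% for features with 20 to under 100 counts and 95.03% for those with 10000 or more.

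With RSA, 639 features were higher and 640 were lower by the rule of size, which together are 8.55% of those compared. On the log2(TPM + 1) scale 442 were at least 2-fold higher and 340 lower. On the scaled counts, 258 of the features past the rule were at least 4-fold higher and 261 lower. At least 10-fold, 100 of them were higher and 94 lower. The higher features took 0.916% of the mock counts and 4.21% of the RSA counts. The lower features took 0.670% of the mock counts and 0.114% of the RSA counts. The lower features were also scarcer, with a median of 40 counts over both libraries against 58 for the higher ones. In these libraries 114 of the higher features had no count in mock and 175 of the lower features had none with RSA. A ratio past the rule compares these libraries, not the conditions.

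The balance between higher and lower features changed with abundance. In the class of 20 to under 100 counts, 425 features were higher and 539 were lower, so that 44.1% of the changed features were higher (95% Clopper-Pearson interval 40.9% to 47.3%). At 100 to under 1000 counts, 153 were higher and 93 lower. At 1000 to under 10000 counts, 55 were higher and 8 lower, a share of 87.3% (76.5% to 94.4%). These intervals take features as independent draws, which features of the same cluster are not, so they are likely too narrow. At 10000 counts or more, 6 were higher and 0 lower. The excess of higher features at 1000 counts or more was present under each scaling, with 61 higher and 8 lower under TMM and 54 higher and 10 lower under library totals. The excess of lower features at 20 to under 100 counts was also present under each scaling, with 357 higher and 622 lower under library totals. It was small once each abundance class was centred on its median ratio (475 higher and 495 lower). Centring itself shifts calls in this class towards higher, since its median log2 ratio was -0.054. The near balance is therefore partly set by that step.

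**Figure D1:**
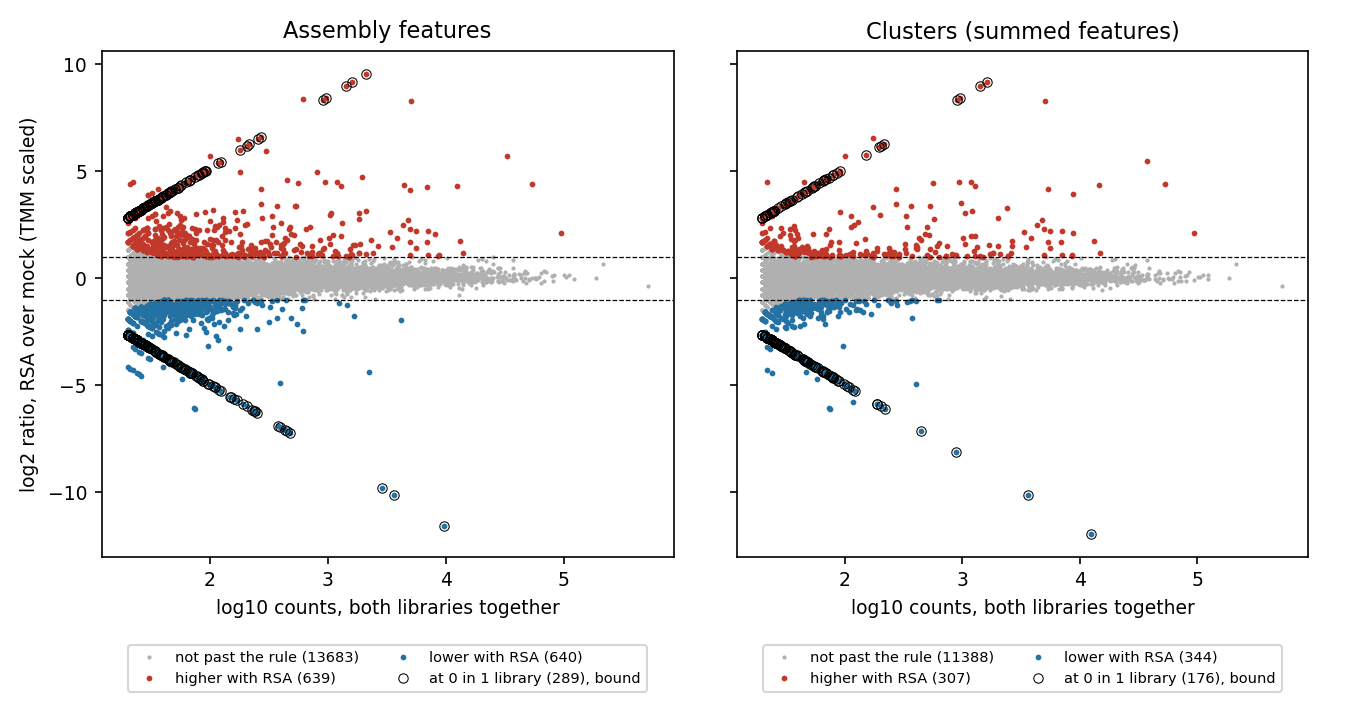
Log2 ratio of RSA over mock (vertical axis, TMM scaled) against log10 of the counts in both libraries together (horizontal axis), for 14962 assembly features (left) and 12039 clusters of summed features (right). Each point is a feature or cluster, dashed lines mark 2-fold, red and blue points are past the rule of size, and black circles are at 0 in 1 library and drawn at the bound set by 3 counts. Abundant features past the rule lie mostly above the upper line.

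Changed features were more frequent among features that share a cluster with others. Of the features alone in their cluster 5.13% were past the rule (376 of 7336), and of those with cluster mates 11.8% were (903 of 7626). This comparison was not matched for abundance. Over all compared features the share past the rule was 19.3% at 20 to under 100 counts and 3.43% at 100 to under 1000. Summed over clusters, 12039 clusters had at least 20 counts, and 307 were higher and 344 lower with RSA. Of these, 55 higher clusters had no count in mock and 121 lower clusters had none with RSA. That leaves 252 higher and 223 lower clusters with counts in both libraries. Of the 903 changed features with mates, 232 lay in a cluster that was past the rule in the same direction, and 671 lay in a cluster that was not past it. Summed with their mates, 667 of the 903 came under 2-fold. In 100 draws that gave each the mates of another feature with like counts and a like mate total, a median of 667 did (651 to 686). The summed counts correlated across clusters with Pearson's r = 0.970 and Spearman's rho = 0.972.

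Among abundant clusters nearly all of the change was upward. Of 2609 clusters with at least 1000 counts over both libraries, 54 were higher with RSA and 2 were lower, and under library totals 45 were higher and 4 lower. Of the 54 higher clusters, 32 were 2- to 4-fold higher, 12 were 4- to 10-fold higher and 10 were at least 10-fold higher. Both lower clusters had no count with RSA. Apart from them, no cluster among the 1508 with at least 1000 mock counts was lower by more than 1.98-fold, or 2.11-fold under library totals. At 100 to under 1000 counts 40 clusters were lower, 30 of them with counts in both libraries. In the class of 20 to under 100 counts the balance was the opposite, with 172 clusters higher and 302 lower.

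A few clusters held most of the counts gained by the clusters past the rule. The 307 higher clusters together gained 275551 counts, of which 51.2% was in 3 clusters. These counts were neither scaled nor divided by length, so 51.2% is a share of reads and not of transcripts. These 3 took 0.248% of the mock counts and 1.83% of the RSA counts. The largest gain was in a single-feature cluster of 5325 nt, which had 18588 counts in mock and 75694 with RSA, a scaled ratio of 4.33 (95% counting interval 4.27 to 4.41). A single-feature cluster of 3437 nt had 2597 counts in mock and 51021 with RSA, a ratio of 20.9 (20.1 to 21.8). A cluster of 2 features, the longer of 4607 nt, had 879 counts in mock and 36419 with RSA, a ratio of 44.1 (41.2 to 47.2). The highest ratio from a nonzero mock count among clusters with at least 1000 RSA counts was in a single-feature cluster of 1833 nt, with 17 counts in mock and 5021 with RSA, a ratio of 314 (196 to 540). These 4 clusters were singled out after their values were seen. The longest features of the 10 clusters that were at least 10-fold higher measured 1240 to 4607 nt.

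**Figure D2:**
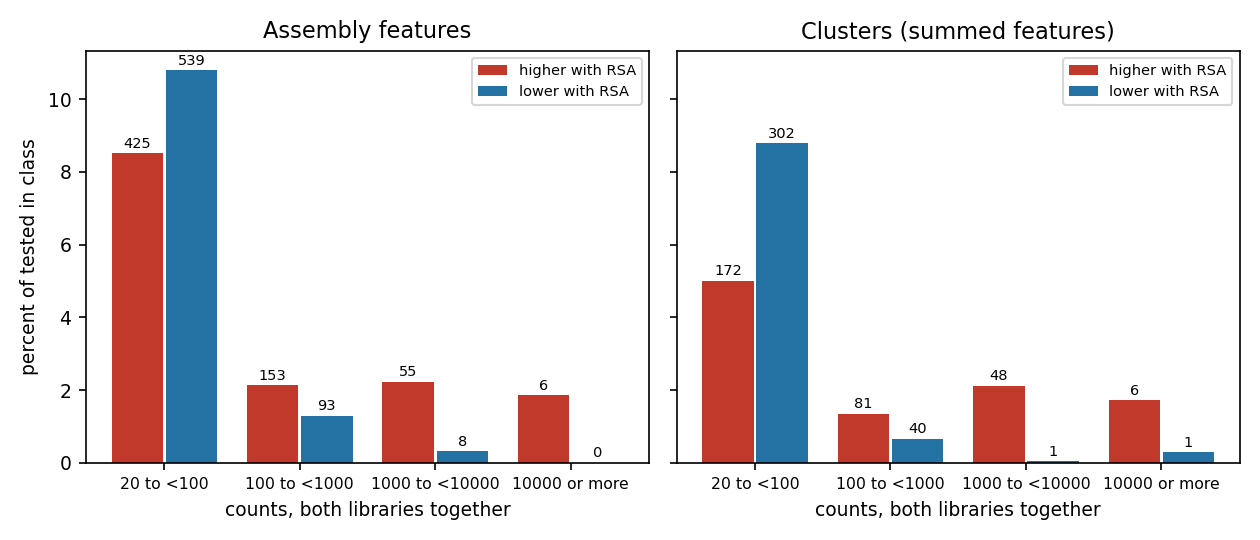
Percent of the compared features (left) and clusters (right) that were higher (red) or lower (blue) with RSA, by the counts in both libraries together, with the number of features or clusters above each bar. There is 1 library per group, so the bars have no error. At 1000 to under 10000 counts 48 clusters were higher and 1 was lower, and at 20 to under 100 counts 172 were higher and 302 lower.

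The 2 features with the highest lower bound were TRINITY_DN13584_c0_g2 and TRINITY_DN27009_c0_g1. TRINITY_DN13584_c0_g2, of 3118 nt, had 0 rounded counts in mock and 2116 with RSA (51.8 TPM), at least 751-fold higher. Its only cluster mate, of 3116 nt, went the other way, with 2144 counts in mock and 96 with RSA, and the cluster sums were 2144 and 2212, a ratio of 1.098 (1.03 to 1.17). The summed cluster was not past the rule. TRINITY_DN27009_c0_g1, of 1240 nt, had 0 counts in mock and 1615 with RSA (116 TPM), at least 573-fold higher, and its mate of 421 nt had 0 counts in both libraries.

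The 2 features with the lowest upper bound were TRINITY_DN8460_c2_g2 and TRINITY_DN13509_c0_g1. TRINITY_DN8460_c2_g2, of 666 nt, had 9739 counts in mock (1615 TPM) and 0 with RSA, at least 3050-fold lower. Its mate, of 417 nt, had 2865 counts in mock and 0 with RSA, so that the cluster was at least 3947-fold lower. TRINITY_DN13509_c0_g1, alone in its cluster with 5 transcripts, had 3618 counts in mock (52.9 TPM) and 0 with RSA, at least 1133-fold lower. These are the 2 lower clusters with at least 1000 counts. Whether any of the 4 features encodes a cytochrome P450, a redox partner or another enzyme that acts on steroids was not analysed here, since the files pair their identifiers with no name or sequence.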

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

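The steps that use clusters, read partitions, abundance classes or the removal of zeros were chosen after seeing the data. Of 69 alternative values, 42 stayed close to the main value (counts within 1.5-fold, percentages within the 95% interval, the correlation within 0.01, bounds within their counting interval) and 27 moved. The direction of all 4 named features stayed, but the balance of higher and lower calls, which was even for features (639 and 640) and leaned to lower for clusters (307 and 344), did not. Library totals, DESeq2 and upper quartile gave 537 to 614 higher and 660 to 745 lower features, and the percent of changed features that were higher, 49.96% in the main setting, was 41.9% under library totals and 44.7% under DESeq2 size factors. Centring on each abundance class's median gave 668 higher, 607 lower and 52.4%. The count minimum and the size rule set the number of calls. At least 10 counts gave 882 higher and 1121 lower features, at least 1 count gave 1168 higher and 1592 lower, and at least 100 counts gave 214 higher and 101 lower. A 4-fold rule gave 258 higher and 261 lower, an interval wholly beyond 2-fold gave 299 higher and 247 lower, and TPM plus 1 gave 442 higher and 340 lower. Counts summed over clusters gave 307 higher, 344 lower and 47.2% higher, counts summed over the wider read partitions gave 291, 331 and 46.8%, and removal of features at 0 in a library gave 525, 465 and 53.0%. For clusters, 4-fold gave 116 higher and 147 lower, and at least 100 counts gave 135 higher and 42 lower, which turned the balance to higher. Removal of clusters at 0 in a library gave 252 higher and 223 lower. That removal selects on the change itself and takes out 121 lower against 55 higher clusters, so it is no check of the balance. The correlation across features was 0.914 with a pseudocount of 0.1 CPM and 0.970 over clusters. The causes of these shifts were not tested, except that stricter rules leave fewer features. TRINITY_DN13584_c0_g2 was at least 751-fold higher as a feature and 1.098-fold higher as a cluster. The other 3 named features kept bounds set by the floor above 500-fold. The lower interval limit for TRINITY_DN27009_c0_g1 in the main setting was 465-fold. Alternatives for the gene lists and for P450 genes were not run, because the lists could not be matched, and leaving out replicates was not possible with 1 library per group. Simulated 2-fold changes over all compared counts were recovered in 50.8% of cases, as a rule set at 2-fold allows.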

Other observations

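Several clusters at 0 with RSA were short. With at least 100 counts, 12 clusters had no count with RSA and 8 had none in mock. Of the 12, 6 were shorter than 350 nt (50%, 95% Clopper-Pearson interval 21.1% to 78.9%). Their lengths were 277 to 320 nt and their mock counts 118 to 888. None of the 8 was that short (0 of 8, interval 0% to 36.9%). The limit of 350 nt was not planned and was set after the values were seen. Among all 8604 clusters with at least 100 counts, 0.814% were that short. At the lower minimum of 20 counts, 16 of 121 clusters at 0 with RSA were that short (13.2%, 95% Clopper-Pearson interval 7.75% to 20.6%), 3 of 55 at 0 in mock (5.45%, 1.14% to 15.1%) and 1.74% of all 12039. Whether length differs between the 2 directions was not tested. The clusters at 0 in mock included 2 single-feature clusters of like length and count, of 8292 nt with 912 RSA counts and of 8350 nt with 957 RSA counts.

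The length that RSEM averages over a feature's transcripts differed in few features. Of 2259 features with 2 or more transcripts and at least 100 counts in each library, 126 (5.58%) had an average length that differed by at least 10% between libraries, 55 longer and 71 shorter with RSA. A difference of at least 25% was found in 36 features. Of the 126, 3 were past the 2-fold rule. These lengths carry no error in the files, and they do not move when use shifts between transcripts of like length.

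All tests in this part were chosen after the results were seen, and the tests on cluster mates were revised after earlier versions had been run. Of 903 changed features with mates, 667 came under 2-fold in the cluster sum. In 100 draws that gave each feature the mates of another with like counts and a like mate total, a median of 667 did (651 to 686), so dilution by unrelated mates is enough for the number of lost calls. The same draws with every mate turned to change against its feature gave 734 to 757, so a broad exchange of reads would have shown in this number, but one in few clusters might not. Of the 903, 197 had mates whose summed counts changed in the opposite direction by 0.5 to 2 times as much, against at most 147 (median 130) in the draws. Mates that changed as much in the same direction were fewer than in any draw, at 107 against 114 to 158. A draw could give a feature its own counts, by way of its own mate, which adds to the same direction. The smallest set to draw from held 3 other features. The number of offsetting mates thus lay above all draws of unrelated mates. The draws take the 903 features as independent, whereas changed mates that offset each other both enter the 197. The range of the draws is therefore likely too narrow, and how far dilution by unrelated mates accounts for the excess is not settled. A candidate explanation for the excess is that reads of related features were divided differently in the 2 libraries. The opposite changes of TRINITY_DN13584_c0_g2 and its mate could have arisen in this way, but this was not shown. A switch between related genes brought about by RSA was not tested, with 1 library per group.

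The 2 abundant clusters at 0 with RSA were far from other clusters of their abundance, since the steepest fall among the others with at least 1000 mock counts was 1.98-fold. Among clusters with at least 100 mock counts, however, falls to a nonzero count reached 54.5-fold, so RNA of a source present only in the mock library and a response to RSA cannot be told apart. If RSA had stopped transcription of the 2 clusters at 0 with RSA, a half-life of at most 10.04 min for the first and 11.8 min for the second would take them to the floor within 2 h. With a single time point the files hold no value that decides this. For the 2 abundant clusters at 0 in mock, RNA of a source present only in the RSA library and induction by RSA cannot be told apart, for the same reason. Other clusters with at least 1000 RSA counts were up to 314-fold higher, which does not decide it, since their origin is not known either.

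Low-count features held more of the mock library. The 26022 features with 1 to 19 counts over both libraries summed to 66169 counts in mock and 43534 with RSA, a ratio of 0.658 (95% counting interval 0.650 to 0.666). Depth does not account for this, since the ratio of library totals was 1.002. The sums are unscaled, and the TMM size ratio of 0.939 would cover only part of the shortfall. An assembly of the mock reads only does not account for it either, since 55 clusters with at least 20 RSA counts had none in mock. An assembly to which mock reads merely contributed more was not tested. The ratio was lowest in short features, at 0.489 below 300 nt, 0.611 from 300 to under 500 nt, 0.774 from 500 to under 1000 nt and 0.838 (0.806 to 0.871) at 1000 nt or more. Fragments were longer with RSA (length minus effective length 275 against 271 nt), which lowers counts on short features and may contribute there, but the effective lengths had ratios of only 0.879 below 300 nt and 0.995 at 1000 nt or more. RNA or DNA of another source in the mock library and a loss of scarce transcripts with RSA may both contribute and were not tested, because the files hold no sequences.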
